A study of Mus musculus with 6 samples.

How the data were processed

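Total RNA from mouse bone marrow-derived dendritic cells was extracted with TRIzol and made into libraries with KAPA Hyper Prep kits, per the labels' protocols. The 6 libraries fall into 2 groups by the treatment label, 3 with DMSO (vehicle) and 3 with AZD1775. Dose, time of exposure, the cytokines of the culture and the strand setting of the counting are not given in the sources used here.

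The authors deposited whole-number read counts per gene for each library, without normalization. The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and the build mm10, with no role or order. The authors also deposited FPKM values, rounded to 2 decimals. These were recomputed here from the count, the exonic length given in the table and the sum of the count column, and matched to within 0.005 FPKM for 100% of values. The table holds 56691 genes under Ensembl identifiers, 2639 of them without a symbol. Of these identifiers, 52073 are in GENCODE M21, which is on GRCm38, the assembly also called mm10. Only 1472 of them (2.83%) have the same start and end there, and 48911 (93.9%) have the same length at another position. The table's own coordinates are therefore not used, and positions are those of M21 by identifier.

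Library totals ran from 14271467 to 19665958 counts, so that 3 counts, the most that a count of 0 allows, are 0.153 to 0.21 CPM by library, for counting error alone. Rn18s-rs5, a row for ribosomal RNA sequence, took 2.17%, 3.90% and 1.58% of the counts in vehicle 1, 2 and 3 and 1.95%, 2.53% and 1.48% in AZD1775 1, 2 and 3. Pairs of libraries differed by 11.1 to 65.1 times the chi-square that sampling noise gives, so none was counted as a duplicate of another.

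Counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr with its minimum count of 10, TMM factors, and the quasi-likelihood fit and test, two-sided, with no covariate. P-values were adjusted by Benjamini and Hochberg over the 13657 genes kept, with a threshold of 0.05. The estimated biological coefficient of variation was 14.5%. The design fixed beforehand named limma on log2(FPKM + 1) as the test unless the table held counts, in which case edgeR took its place and limma became an alternative. CPM are counts scaled by the library total and TMM factor. Fold changes are edgeR's, as log2 of AZD1775 over vehicle, and their SE comes from the same fit. Genes of families with near-identical copies, such as immunoglobulins, histones and MHC class I, can share reads and are less certain. Without a stated strand setting the reads of overlapping antisense genes cannot be told apart.

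The alternatives to the test, the 44 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 kept members (39 of 44) were tested on log2 CPM with camera of limma 3.58.1 at its preset correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation stands beside it, as does fry, which asks whether a list's genes move, on balance, in 1 direction. Members were also adjusted over each list alone. Named genes were of 3 kinds. The first was up to 12 in each direction with an adjusted p under 0.05, a mean FPKM of at least 5, a symbol that is not a predicted model and no overlap between groups, a rule that gave 0 genes. The second was up to 4 members of each list with the smallest unadjusted p (157 genes). The third was 26 genes fixed by name, of which 25 were tested. Ckap2 falls outside this rule and was named after its values were seen.

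The alternatives were DESeq2 1.42.0 with its size factors, edgeR without the filter, limma on log2 FPKM with pseudocounts of 0.1, 0.5 and 1, filters at a mean FPKM of 0.5 and 1, other scalings and variance models, a fold change threshold of 1 on the log2 scale, the replicate number as a block, and leaving out each library in turn. The closing section gives their effect. The code was tested on counts simulated for the comparison of AZD1775 with vehicle, over 13657 genes with 200 changed. The simulation used the real depths and a spread set by expression level alone, where real genes of like expression differ in spread. It left the genes of lowest expression unchanged. The shares recovered may therefore be too high for the real data. EdgeR recovered 50% of the genes changed 1.5-fold, 86% at 2-fold, 98% at 3-fold and 100% at 4-fold. It made 181 calls, 14 of them false, and 0 calls where nothing was changed. Of 10 simulated lists of 20 genes changed 1.3-fold, with genes drawn independently of each other, which real genes are not, camera called 10 with either correlation, and fry 10. Of 39 unchanged lists camera's preset called 1.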

Results

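Messenger RNA was measured in mouse bone marrow-derived dendritic cells, antigen-presenting cells grown in culture from marrow progenitors. The cells had received either the solvent DMSO, called vehicle here, or AZD1775 (adavosertib), an inhibitor of the kinase WEE1. WEE1 restrains entry into mitosis by phosphorylating CDK1. Each treatment had 3 libraries, and the comparison of AZD1775 with vehicle asks how WEE1 inhibition changes gene expression in dendritic cells, which the series title ties to antitumour immunity. The vehicle libraries 1, 2 and 3 held 18547098, 18913009 and 19665958 gene counts, and the AZD1775 libraries 14271467, 17054122 and 15370036, so each AZD1775 library was shallower than each vehicle library. Nothing in the labels says that the libraries came from separate mice or cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

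As lists, genes of mitosis fell in the AZD1775 libraries, p53 target genes, targets of the stress-response transcription factor ATF4 and B cell markers rose, and genes of the endoplasmic reticulum unfolded protein response fell. These calls are of camera at its preset correlation, and with an estimated correlation between genes it called 0 of the 39 lists tested, with 6 at an unadjusted p under 0.05. The mean log2 fold changes were -0.39 over 38 mitosis genes, 0.32 over 27 p53 targets, 0.42 over 31 ATF4 targets, 0.85 over 9 B cell markers and -0.20 over 19 unfolded protein response genes. In each of these 5 lists, all 3 AZD1775 libraries lay on the same side of all 3 vehicle libraries. The design fixed beforehand did not single out these 5. Of all 39 lists tested, 10 were parted in this way, where chance gives 10%. Of 39 lists tested with camera, 24 passed the adjusted threshold, 16 higher and 8 lower in AZD1775. In 9 of the 24 the library scores of the groups did not overlap, and in the other 15 they did. In fry 2 passed it, the p53 targets and the unfolded protein response genes.

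No single gene passed the test. Of 13657 genes, edgeR called 0 with Benjamini-Hochberg adjustment, with a smallest adjusted p = 0.291. At an unadjusted p under 0.05 there were 1124 genes, 783 higher and 341 lower in AZD1775, where chance gives 683. DESeq2 called 63 genes, 52 higher and 11 lower, limma on log2 FPKM called 0, and edgeR without its filter on low counts called 478, 396 higher and 82 lower. Of the 63 DESeq2 calls, 25 belonged to a tested list, Apoe and Ctsd to 2 lists each. B cell markers had 8 of them, while mitosis, the G2/M checkpoint, p53 targets, ATF4 targets, macrophage markers, pattern recognition receptors and lipid genes had 2 each. Plasmacytoid dendritic cell markers, NRF2 targets, the lysosome, MHC class II and nucleic acid sensing had 1 each, and 26 of the 39 lists had 0. The DESeq2 calls outside the lists included further immunoglobulin genes, all higher in AZD1775, whose reads can be shared. Of the genes at an unadjusted p under 0.05, 69.7% were higher in edgeR and 60.1% in limma on log2(FPKM + 1). In limma it was 48.9% after quantile normalization, 53.5% after median-of-ratios scaling of FPKM and 57.1% with FPKM rescaled to equal sums. The 3 values of the groups did not overlap for 1637 genes, or 11.99%, where chance gives 10%. Without vehicle 2 the count at an unadjusted p under 0.05 was 681, and without AZD1775 3 it was 540. The groups were not parted on the first principal component, which held 43.8% of the variance: vehicle 2 lay at -38.6, vehicle 1 at -14.5, AZD1775 1 at -2.74, vehicle 3 at 5.98, AZD1775 2 at 16.3 and AZD1775 3 at 33.5.

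**Figure D1:**
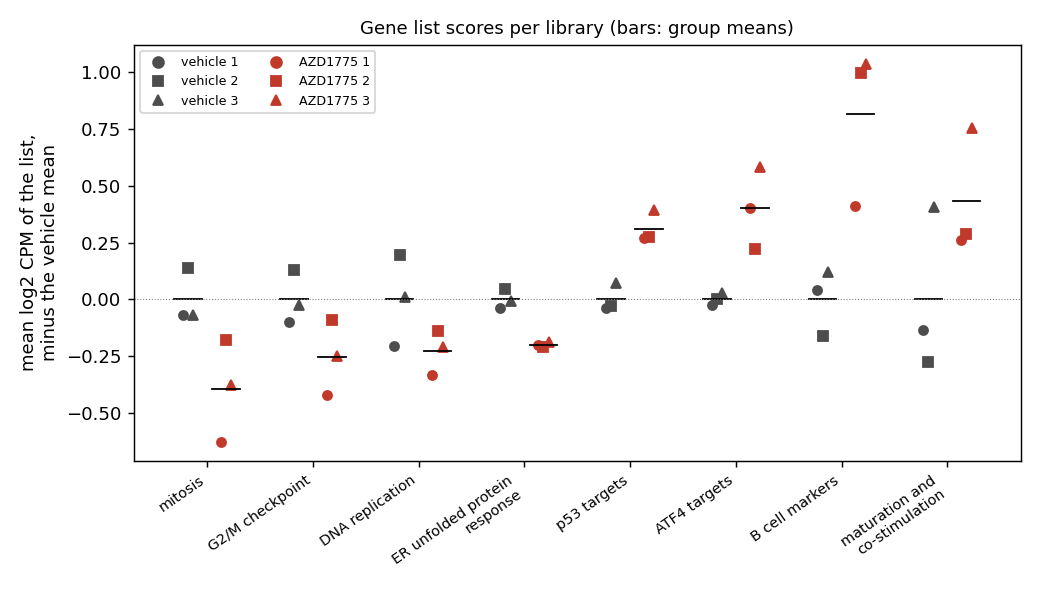
Mean log2 CPM, the library-scaled count, of the tested members of 8 gene lists in each library, as a difference from the vehicle mean. Points are libraries and bars are group means. The AZD1775 libraries lie between 0.27 and 0.39 for p53 targets, above the highest vehicle library at 0.07, while the groups overlap for maturation and co-stimulation.

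Genes of cell division had lower values in AZD1775. All 38 mitosis genes were lower, 23 of them at an unadjusted p under 0.05. Kif4, a chromosome-condensing kinesin, stood at 36.0 ± 2.87 CPM in vehicle and 22.4 ± 3.29 in AZD1775 (SD, n = 3). Racgap1, needed for cytokinesis, stood at 105.7 ± 9.11 and 71.4 ± 9.02 CPM, and the mitotic kinase gene Aurkb at 49.9 ± 6.49 and 33.6 ± 4.18 CPM. The mitosis list fell (camera, adjusted p = 2.43e-23), with adjusted p = 0.237 with an estimated correlation. Over all genes edgeR called 0 of its members, and 22, all lower, when adjusted over the list alone.

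The fixed list of G2/M checkpoint kinases and their regulators also holds the E cyclins. Of its 19 genes, 15 were lower, with a median log2 fold change of -0.16 over the list. The list fell (camera, adjusted p = 5.09e-06, and adjusted p = 0.399 with an estimated correlation). The groups overlapped, with vehicle 1 at a score of -0.102 against the vehicle mean, below AZD1775 2 at -0.092. The cyclins led this list. Ccnb2, cyclin B2, which activates CDK1, stood at 55.2 ± 11.99 CPM in vehicle and 28.7 ± 3.57 in AZD1775 (SD, n = 3), 1.92-fold lower, with a log2 fold change of -0.94 ± 0.17 (SE; edgeR adjusted p = 0.291). Ccna2, Ccne1 and Ccne2, the cyclins A2, E1 and E2, had log2 fold changes of -0.70, -0.59 and -0.72. These 4 cyclins were the members called when adjusted over the list alone, and 0 were called over all genes. The drug's target Wee1 stood at 19.2 ± 2.86 and 22.1 ± 3.61 CPM, a log2 fold change of 0.21 ± 0.16 (SE; edgeR adjusted p = 0.823). Its relative Pkmyt1 had a log2 fold change of -0.23, Chek1, a checkpoint kinase, 0.02, and Cdk1 itself -0.38 (edgeR adjusted p = 0.769, 0.992 and 0.594). On GRCm38, Wee1 (ENSMUSG00000031016) lies on chromosome 7 from 110122046 to 110143286 and Cdk1 (ENSMUSG00000019942) on chromosome 10 from 69335146 to 69352938, both protein-coding.

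Genes of DNA replication were lower for 38 of 40 members, 8 of them at an unadjusted p under 0.05, and the list fell (camera, adjusted p = 4.61e-11, and adjusted p = 0.399 with an estimated correlation). Rrm1 and Rrm2, subunits of ribonucleotide reductase, had log2 fold changes of -0.42 ± 0.14 and -0.53 ± 0.16 (SE), and the thymidylate synthase gene Tyms -0.44 ± 0.15. Of 25 genes of homologous recombination and the Fanconi pathway, 21 were lower, among them the helicase gene Brip1 at -0.47 and Rad51ap1 at -0.40, and the list fell (camera, adjusted p = 4.42e-05, and adjusted p = 0.427 with an estimated correlation). The replication-dependent histones, which share reads with near-identical copies and are uncertain for that reason, were lower for 13 of 14 members, H1f3 at -1.3015, and fell as a list (camera, adjusted p = 0.00165, and adjusted p = 0.411 with an estimated correlation). In these 3 lists edgeR called 0 members over all genes and 0 adjusted over the list alone, with 8, 3 and 1 members at an unadjusted p under 0.05, and DESeq2 called 0. The groups overlapped in each. Vehicle 1 scored -0.206 for replication and -0.099 for recombination, below AZD1775 2 at -0.139 and 0.013. For the histones vehicle 3 scored -0.593, below AZD1775 1 and 2 at -0.352 and -0.217. The histone score was highest in vehicle 2 (0.508) and lowest in AZD1775 3 (-0.899). These libraries had the most and the least Rn18s-rs5 reads (3.90% and 1.48%). AZD1775 2 broke that order, at 2.53% against 2.17% for vehicle 1, which scored 0.085. Whether the share of ribosomal RNA reads bears on the histones was not tested. Without vehicle 2, the mean of the replication genes moved from -0.23 to -0.12 and that of the histones from -0.56 to -0.21, the latter no longer past the threshold (camera, adjusted p = 0.111). The histones stood at -0.84 without vehicle 3 and at -0.85 without AZD1775 2. Without AZD1775 1, the recombination genes moved from -0.19 to -0.09 (camera, adjusted p = 0.0975), and without AZD1775 2 to -0.30.

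**Figure D2:**
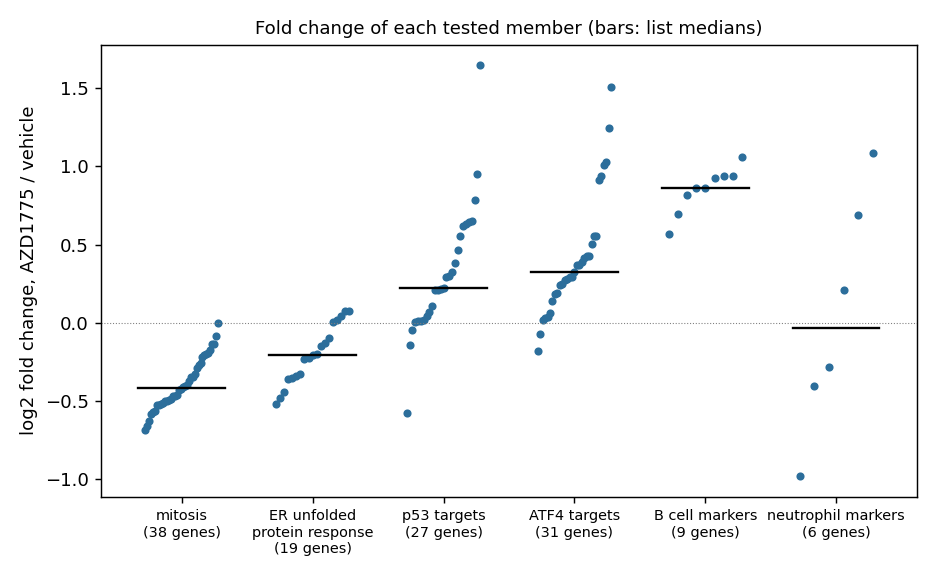
Log2 fold change of AZD1775 over vehicle for each tested member of 6 gene lists, ordered by size within a list. Bars are list medians, at -0.42 for mitosis, -0.21 for the unfolded protein response, 0.22 for p53 targets, 0.33 for ATF4 targets, 0.86 for B cell markers and -0.03 for neutrophil markers.

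Targets of the tumour suppressor p53 had higher values for 24 of 27 members, 10 of them at an unadjusted p under 0.05. Phlda3, which restrains AKT signalling, stood at 0.97 ± 0.32 CPM in vehicle and 3.05 ± 0.79 in AZD1775 (SD, n = 3), 3.13-fold higher. Trp53inp1, a cofactor of p53, stood at 68.2 ± 6.001 and 100.1 ± 11.7 CPM, and Pmaip1, which encodes the pro-apoptotic protein NOXA, at 160.8 ± 14.6 and 209.2 ± 11.3 CPM. Cdkn1a, the cell cycle inhibitor p21, stood at 82.9 ± 31.5 and 143.0 ± 38.5 CPM, with vehicle 3 at 118.4 above AZD1775 2 at 113.5 (edgeR adjusted p = 0.52). Trp53 itself had a log2 fold change of -0.10 (edgeR adjusted p = 0.86). The list rose (camera, adjusted p = 1.93e-06; fry, adjusted p = 0.029), with adjusted p = 0.0944 with an estimated correlation. Adjusted over the list alone, edgeR called 8 members, 7 higher and 1 lower, and over all genes 0. The lower member, Ckap2, chosen after its values were seen, encodes a protein of the mitotic spindle.

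ATF4 targets were higher for 29 of 31 members, 11 of them at an unadjusted p under 0.05. Asns, asparagine synthetase, had the smallest p of all genes: 3.40 ± 1.05 CPM in vehicle and 9.70 ± 1.22 in AZD1775 (SD, n = 3), 2.84-fold higher, with a log2 fold change of 1.505 ± 0.234 (SE; edgeR adjusted p = 0.291, DESeq2 adjusted p = 9.07e-05). Phgdh, which opens serine synthesis, stood at 5.39 ± 1.02 and 10.2 ± 1.59 CPM, the eIF2 phosphatase subunit Ppp1r15a at 65.4 ± 3.97 and 92.7 ± 16.4, and the methionyl-tRNA synthetase gene Mars1 at 52.0 ± 1.82 and 67.3 ± 4.71. The list rose (camera, adjusted p = 8.15e-10), with adjusted p = 0.237 with an estimated correlation. Those 4 genes were called when adjusted over the list alone, and 0 over all genes. Atf4 and Ddit3 had log2 fold changes of 0.14 and 0.19 (edgeR adjusted p = 0.86 for each).

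Of 19 genes of the unfolded protein response, 14 were lower, 8 of them at an unadjusted p under 0.05, and none was higher at that p. Hyou1 stood at 210.4 ± 7.68 CPM in vehicle and 165.1 ± 5.55 in AZD1775 (SD, n = 3), and Hsp90b1 at 838.2 ± 62.7 and 667.7 ± 22.6. Both encode chaperones of the endoplasmic reticulum. The protein disulfide isomerase gene Pdia6 stood at 300.4 ± 46.0 and 221.2 ± 21.7 CPM. The list fell (camera, adjusted p = 1.32e-06; fry, adjusted p = 0.00913), with adjusted p = 0.0944 with an estimated correlation, and edgeR called 0 members over all genes and 0 adjusted over the list alone.

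**Figure D3:**
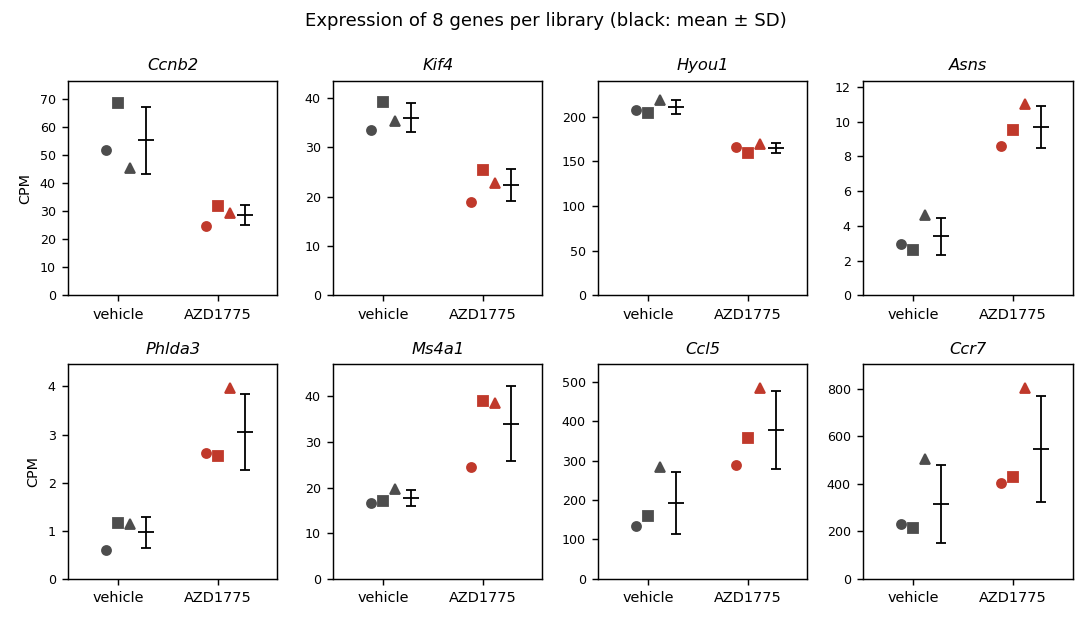
Expression of 8 genes in CPM in each library, with symbols for replicates 1 to 3 and the mean ± SD of each group in black. Ccnb2, Kif4 and Hyou1 are lower in the 3 AZD1775 libraries than in the 3 vehicle libraries, Asns, Phlda3, Ms4a1 and Ccl5 are higher in them, and for Ccr7 the groups overlap, with vehicle 3 at 505.4 CPM.

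Chemokines were higher for 14 of 15 members, 8 of them at an unadjusted p under 0.05, and the list rose (camera, adjusted p = 3.95e-07, and adjusted p = 0.226 with an estimated correlation). Ccl5, which attracts T cells, stood at 192.8 ± 79.4 CPM in vehicle and 377.7 ± 99.3 in AZD1775 (SD, n = 3), 1.96-fold higher (edgeR adjusted p = 0.427). Ccl4 stood at 0.67 ± 0.08 and 1.57 ± 0.32 CPM, Cxcl3 at 0.70 ± 0.18 and 2.42 ± 1.68, and Ccl9 at 126.6 ± 33.6 and 193.8 ± 37.8. These 4 were called when adjusted over the list alone, and 0 over all genes. Against the vehicle mean, the chemokine score was -0.18, -0.07 and 0.25 in vehicle 1, 2 and 3 and 0.37, 0.64 and 0.84 in AZD1775 1, 2 and 3, and that of macrophage markers, which also rose, -0.24, -0.08 and 0.32 and 0.24, 0.58 and 0.71. The interferon-induced chemokine genes Cxcl10 and Cxcl9 had log2 fold changes of 0.69 and 0.10 (edgeR adjusted p = 0.692 and 0.973).

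Inflammatory cytokines and their regulators were higher for 17 of 20 members, and the list rose (camera, adjusted p = 3.21e-06, and adjusted p = 0.237 with an estimated correlation). Il10, which encodes an anti-inflammatory cytokine, and Nfkbiz, a regulator of NF-kB, were called when adjusted over the list alone, at log2 fold changes of 1.56 ± 0.40 and 0.57 ± 0.15 (SE), and 0 were called over all genes. The groups overlapped in this list, with vehicle 3 at a score of 0.36 against the vehicle mean, above AZD1775 1 at 0.25, as they did for macrophage markers. Tnf stood at 5.41 ± 0.28 CPM in vehicle and 6.83 ± 0.74 in AZD1775 (SD, n = 3), Il12b at 36.5 ± 22.95 and 55.1 ± 27.0, and Il6 at 0.81 ± 0.67 and 0.79 ± 0.48 (edgeR adjusted p = 0.691, 0.781 and 0.994). Co-inhibitory and tolerogenic genes were higher for 16 of 20 members and rose as a list (camera, adjusted p = 0.00143, and adjusted p = 0.237 with an estimated correlation). Adjusted over the list alone, Il10 and the immune checkpoint gene Cd276, at 0.11 ± 0.06 and 0.81 ± 0.09 CPM, were called, and 0 over all genes. The vehicle values of Cd276, 0.162, 0.11 and 0.05 CPM, lay at or below what a count of 0 allows. DESeq2 called 0 members of this list. At a mean FPKM of at least 1 the co-inhibitory list did not pass, and its mean log2 fold change moved from 0.51 to 0.28 (camera, adjusted p = 0.0879). Cd274, which encodes PD-L1, stood at 12.8 ± 7.73 and 22.7 ± 8.82 CPM (edgeR adjusted p = 0.653). Without AZD1775 3 the mean of the cytokine list moved from 0.53 to 0.30, and with vehicle 2 also left out to 0.24. It was 0.35 without the filter on low counts, 0.33 at a mean FPKM of at least 1 and 0.30 in limma on log2(FPKM + 1).

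Genes of dendritic cell maturation and co-stimulation were higher for 13 of 16 members, and the list rose (camera, adjusted p = 4.50e-05, and adjusted p = 0.375 with an estimated correlation). Cd80, a co-stimulatory ligand that is also among the p53 targets, stood at 11.3 ± 1.94 CPM in vehicle and 17.4 ± 1.47 in AZD1775 (SD, n = 3) and was the 1 member called when adjusted over the list alone, with 0 over all genes. Cd86, the other ligand of CD28, stood at 188.8 ± 11.8 and 180.2 ± 11.4 CPM, and Cd40 at 37.6 ± 14.7 and 55.4 ± 23.04 (edgeR adjusted p = 0.922 and 0.699). Ccr7, the receptor that guides dendritic cells to lymph nodes, stood at 316.4 ± 164.0 and 545.7 ± 223.4 CPM (edgeR adjusted p = 0.594). The libraries differed in this list within each group: against the vehicle mean, vehicle 3 stood at 0.41 and vehicle 2 at -0.28, and AZD1775 3 at 0.75. Macrophage markers also overlapped between the groups, at 0.32, -0.08 and 0.71 in the same libraries. Without vehicle 3 the list's mean moved from 0.41 to 0.76, and without AZD1775 3 to 0.22. With vehicle 2 and AZD1775 3 both left out it was 0.10 (camera, adjusted p = 0.034).

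Interferon-stimulated genes were higher for 33 of 44 members, 12 of them at an unadjusted p under 0.05 with 1 lower, and the list rose (camera, adjusted p = 8.51e-05, and adjusted p = 0.399 with an estimated correlation). The antiviral genes Oas2, Oasl2 and Rsad2 had log2 fold changes of 0.76, 0.52 and 0.66, Ifi205 -0.42, and Isg15 stood at 7.58 ± 1.295 CPM in vehicle and 8.04 ± 0.98 in AZD1775 (SD, n = 3; edgeR adjusted p = 0.956). Called by edgeR were 0 members over all genes and 0 adjusted over the list alone. The groups overlapped, with vehicle 3 at a score of 0.21 against the vehicle mean, above AZD1775 1 at 0.105, as they did for macrophage markers, whose scores rank the libraries in the same order. Without vehicle 1 the list's mean moved from 0.26 to 0.17. Ifnb1, interferon beta, had 0 counts in all 6 libraries, where a count of 0 allows up to 0.21 CPM in the shallowest, counting error alone. The 15 type I interferon genes reached at most 2 counts in any library and were not tested. Cytosolic nucleic acid sensing did not pass (camera, adjusted p = 0.242), with 12 of 20 members higher. Ikbke, a kinase of the interferon pathway, at 1.17 ± 0.31 and 3.48 ± 0.98 CPM, was its 1 call adjusted over the list alone, with 0 over all genes.

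Pattern recognition receptors were higher for 17 of 20 members and rose as a list (camera, adjusted p = 3.35e-05, and adjusted p = 0.399 with an estimated correlation). Nod1 and Clec7a, which encode sensors of bacterial peptidoglycan and fungal glucans, were called when adjusted over the list alone, at log2 fold changes of 1.57 and 0.68, and 0 over all genes. With vehicle 2 and AZD1775 3 both left out the list did not pass (camera, adjusted p = 0.134), with a mean of 0.19 against 0.49. Genes of antigen uptake and cross-presentation were higher for 15 of 21 members and rose as a list (camera, adjusted p = 0.00165, and adjusted p = 0.237 with an estimated correlation), among them Cybb at 0.65 and Mrc1 at 0.84, with 0 calls adjusted over the list alone and 0 over all genes, and 5 members at an unadjusted p under 0.05. Without AZD1775 2 that list did not pass (camera, adjusted p = 0.0526), with a mean log2 fold change of 0.24 against 0.31. The groups overlapped in both lists, with vehicle 3 above AZD1775 1, at scores of 0.29 and 0.135 for the receptors and 0.17 and 0.125 for antigen uptake, as they did for macrophage markers. The MHC class II list did not pass (camera, adjusted p = 0.0908), though it passed in 14 of 25 alternatives, among them without vehicle 2, AZD1775 2 or AZD1775 3 (camera, adjusted p = 0.0149, 0.032 and 0.0394), with 11 of 16 members higher and Ctsd its 1 call adjusted over the list alone, against 0 over all genes. H2-Ab1 stood at 7089 ± 1269 CPM in vehicle and 6690 ± 1088 in AZD1775 (SD, n = 3; edgeR adjusted p = 0.951). The MHC class I list did not pass either (camera, adjusted p = 0.58), with 12 of 23 members higher, but passed without AZD1775 2 (mean log2 fold change 0.20, camera adjusted p = 0.0241). B2m had a log2 fold change of 0.24 and H2-K1 of 0.29 (edgeR adjusted p = 0.664 and 0.673).

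Markers of B cells, which the labels do not name as part of these cultures, were higher for 9 of 9 members, by 0.57 to 1.06 on the log2 scale. Igkc, the kappa light chain constant region, stood at 41.6 ± 4.51 CPM in vehicle and 75.6 ± 13.2 in AZD1775 (SD, n = 3), Ms4a1, which encodes CD20, at 17.8 ± 1.73 and 34.0 ± 8.19, Cd79a at 15.5 ± 1.75 and 29.7 ± 7.85, and the adaptor gene Blnk at 8.41 ± 0.57 and 14.8 ± 0.50. Reads of immunoglobulin genes can be shared between family members, so Igkc is less certain than the others. The list rose (camera, adjusted p = 2.68e-14), with adjusted p = 0.226 with an estimated correlation. Adjusted over the list alone, edgeR called 8 members, and 0 over all genes. AZD1775 1 had the lowest B cell score of its group, at 0.41 above the vehicle mean, against 1.00 and 1.04 in the others.

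Markers of plasmacytoid dendritic cells were higher for 9 of 9 members and rose as a list (camera, adjusted p = 5.12e-06, and adjusted p = 0.237 with an estimated correlation). Ly6d, Spib and Tcf4, the last a regulator of that lineage, were called when adjusted over the list alone, at log2 fold changes of 0.64, 0.83 and 0.36, and 0 over all genes. Ly6d and Spib are also expressed in B-lineage cells. Macrophage markers were higher for 14 of 15 members and rose as a list (camera, adjusted p = 1.86e-06, and adjusted p = 0.237 with an estimated correlation), with 5 calls adjusted over the list alone and 0 over all genes. Among them Apoe, which encodes apolipoprotein E, stood at 16.1 ± 1.35 CPM in vehicle and 31.2 ± 9.37 in AZD1775 (SD, n = 3), and Adgre1, which encodes F4/80, had a log2 fold change of 0.71 ± 0.18 (SE). Markers of cDC1, the cross-presenting dendritic cell subset, were lower for 11 of 12 members and fell as a list (camera, adjusted p = 0.000226, and adjusted p = 0.312 with an estimated correlation), with Gcsam at -0.62 its 1 call adjusted over the list alone and 0 over all genes. Xcr1 and Clec9a, receptors of that subset, stood at 291.5 ± 7.63 and 351.3 ± 29.3 CPM in vehicle and at 243.4 ± 48.1 and 333.8 ± 74.5 in AZD1775 (edgeR adjusted p = 0.686 and 0.954). Without AZD1775 3 the mean of the cDC1 list moved from -0.21 to -0.13.

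Markers of cDC2, the other conventional subset, were higher for 8 of 10 members, among them Irf4 at 0.54 and Sirpa at 0.60, and rose as a list (camera, adjusted p = 0.0244, and adjusted p = 0.411 with an estimated correlation), with 3 members at an unadjusted p under 0.05, 0 calls adjusted over the list alone and 0 over all genes. That list did not pass without vehicle 1 or without AZD1775 2 (camera, adjusted p = 0.213 and 0.278), where its mean moved from 0.26 to 0.14 in each case, and without AZD1775 1 it stood at 0.40. The groups overlapped in it, with AZD1775 1 at a score of -0.113 against the vehicle mean, below vehicle 2 at 0.144. General dendritic cell markers did not pass (camera, adjusted p = 0.664), with 8 of 12 members higher. Markers of monocytes, neutrophils and stromal cells did not pass (camera, adjusted p = 0.838 for each), with 4 of 8, 3 of 6 and 3 of 6 members higher. Median and mean differed in sign for these 3 lists, at -0.0057 and 0.21, -0.03 and 0.05, and 0.0049 and -0.04, and camera's direction followed the mean for the monocyte list alone. The other marker lists kept too few members for a test. Kit of the basophil and mast cell list stood at 202.5 ± 22.8 and 202.8 ± 5.81 CPM, Il5ra and Siglecf of the eosinophil list at 5.85 ± 2.27 and 12.2 ± 3.60 and at 10.5 ± 1.38 and 11.1 ± 2.60, Lck of the T and NK cell list at 5.19 ± 0.41 and 10.2 ± 2.41, and Car2 of the erythroid list at 1.86 ± 1.45 and 2.62 ± 1.86 (SD, n = 3). The remaining T and NK cell genes kept, Cd3g and Cd8a, stood at 0.47 ± 0.25 and 0.89 ± 0.42 and at 1.07 ± 0.12 and 1.21 ± 0.34 CPM.

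Nuclear genes of oxidative phosphorylation were lower for 29 of 29 members, with a mean log2 fold change of -0.16, and fell as a list (camera, adjusted p = 2.78e-06, and adjusted p = 0.471 with an estimated correlation), with 1 member, Uqcrb, at an unadjusted p under 0.05, 0 calls adjusted over the list alone and 0 over all genes. Without vehicle 2 that mean was -0.04 (camera, adjusted p = 0.056), and without AZD1775 1 it was -0.26. With vehicle 2 and AZD1775 3 both left out it was 0.0054 (camera, adjusted p = 0.593). The groups overlapped, with AZD1775 1 at a score of 0, above vehicle 1 at -0.096 and vehicle 3 at -0.122. The NRF2 oxidative stress list was higher for 15 of 18 members and rose (camera, adjusted p = 0.00018, and adjusted p = 0.411 with an estimated correlation), with the glutathione transferase gene Gstm1 at 1.24 ± 0.26 (SE) its 1 call adjusted over the list alone and 0 over all genes, and its mean moved from 0.33 to 0.20 without AZD1775 3. Apoptosis regulators were higher for 16 of 24 members and rose (camera, adjusted p = 0.00119, and adjusted p = 0.408 with an estimated correlation). The member with the smallest p was the pro-apoptotic gene Pmaip1, at 0.38 and with no overlap between groups. The inhibitor genes Birc2 and Birc3 stood at 0.59 and 0.50, with overlap. There were 6 members at an unadjusted p under 0.05, 0 calls adjusted over the list alone and 0 over all genes. The list's mean moved from 0.22 to 0.12 without AZD1775 3. Genes of fatty acid synthesis and lipid efflux were higher for 14 of 21 members and rose (camera, adjusted p = 0.00684, and adjusted p = 0.399 with an estimated correlation), with Lpl, lipoprotein lipase, at 38.0 ± 10.8 and 77.2 ± 16.0 CPM (SD, n = 3) and Apoe the 2 calls adjusted over the list alone, against 0 over all genes. Without vehicle 2 that list did not pass (camera, adjusted p = 0.177), with a mean log2 fold change of 0.24 against 0.32. The groups overlapped in the NRF2, apoptosis and lipid lists. Vehicle 3 scored 0.18, 0.181 and 0.209 in them, against 0.02 for AZD1775 2 in the first, and 0.124 and 0.117 for AZD1775 1 in the others. With vehicle 2 and AZD1775 3 both left out, none of the 3 passed (camera, adjusted p = 0.2625, 0.1355 and 0.323). Apoe is also a macrophage marker.

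The remaining lists did not pass. Camera's adjusted p was 0.0711 for the lysosome, 0.108 for immediate early genes, 0.242 for glycolysis, 0.345 for cytosolic ribosomal proteins, 0.363 for the heat shock response, 0.388 for mitochondrially encoded genes, 0.529 for the hypoxia response and 0.533 for cholesterol biosynthesis. Their numbers of higher members were 18 of 27, 15 of 23, 7 of 20, 6 of 35, 4 of 13, 11 of 15, 6 of 12 and 13 of 23, and edgeR called 0 members of each over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 they had 4, 3, 1, 0, 0, 0, 3 and 0 members. The 3 of the hypoxia list were all higher. Its library scores did not overlap, at -0.051 to 0.028 in vehicle and 0.149 to 0.273 in AZD1775. Leaving out 1 library brought some of these lists past the threshold. The lysosome passed without vehicle 2, AZD1775 2 or AZD1775 3 (camera, adjusted p = 0.0435, 0.00428 and 0.0406) and immediate early genes without vehicle 1, vehicle 2 or AZD1775 2 (camera, adjusted p = 0.0334, 0.0211 and 0.00754), both higher. Without AZD1775 1, glycolysis and the heat shock response passed as lower (camera, adjusted p = 0.0488 and 0.0403), and without vehicle 1 cholesterol biosynthesis as higher (camera, adjusted p = 0.0478). Cytosolic ribosomal proteins passed as higher without vehicle 2 (camera, adjusted p = 0.00393) and as lower without vehicle 3 or AZD1775 1 (camera, adjusted p = 0.00293 and 9.06e-05).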

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

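The settings that thin every library to the smallest total, use RLE factors or library totals alone, leave out Rn18s-rs5 and Lars2, or leave out vehicle 2 and AZD1775 3 together were chosen after seeing the data. The number of genes called was 0 in edgeR, and it was 478 without the filter on low counts, where edgeR's prior degrees of freedom were infinite against 6.3 with the filter, and 63 with DESeq2. It was 0 under the other settings run, including limma's. All 63 DESeq2 genes were among the 478, and 468 of the 478 were among the genes tested with the filter. The number of lists called by camera was 24, and it ranged from 21 to 27 over the alternatives, with 0 called at an estimated correlation in each. The mitosis, p53, ATF4, unfolded protein response and B cell lists were past the threshold with the same sign in 25 of 25 alternatives. Their mean log2 fold changes ranged from -0.51 to -0.28, 0.21 to 0.44, 0.26 to 0.51, -0.23 to -0.16 and 0.67 to 1.00. The G2/M, replication, interferon, cytokine, chemokine, maturation, plasmacytoid and macrophage lists also passed with the same sign in 25 of 25. Passing these alternatives, which reuse the same libraries, therefore does not set the former lists apart. With vehicle 2 and AZD1775 3 both left out, 8 of the 24 lists did not pass, with means of 0.33 for co-inhibitory genes, 0.19 for pattern recognition receptors, 0.10 for apoptosis regulators, -0.09 for cDC1 markers, 0.12 for NRF2 targets, 0.16 for lipid genes, -0.04 for histones and 0.0054 for oxidative phosphorylation. Co-inhibitory genes did not pass at a mean FPKM of at least 1 (mean 0.28, camera adjusted p = 0.0879), nor lipid genes with limma's library weights (mean 0.16, camera adjusted p = 0.256). Means of the cytokine, co-inhibitory, antigen uptake, pattern recognition, histone, lipid and macrophage lists were closer to 0 by more than 1.5 times in limma on log2(FPKM + 1), and those lists were past the threshold there. With limma's library weights the G2/M, replication, recombination and oxidative phosphorylation means were -0.17, -0.13, -0.11 and -0.10, past the threshold. The interferon mean was 0.17 with median-of-ratios scaling and 0.18 with quantile normalization, against 0.26, past it in both. Of lists not past the threshold with edgeR, MHC class II and the lysosome passed in 14 of 25 alternatives each and immediate early genes in 6. Cytosolic ribosomal proteins, not past the threshold with all libraries, turned from a mean of -0.03 to 0.1835 without vehicle 2 and AZD1775 3 and to 0.1235 without vehicle 2 alone, and were at -0.1196 without vehicle 3 and -0.1854 without AZD1775 1, all past it. The cause was not tested. Of 109 named genes, 98 kept their sign in each alternative that tested them. The exceptions were Chek1, Isg15, Cxcl9, H2-Ab1, Il12b, Il6, Clec9a, Kit, Siglecf, Car2 and Cd8a. With the replicate number as a block, edgeR called 0 genes (smallest adjusted p = 0.0836, and 1409 at an unadjusted p under 0.05) and camera 25 lists, the 24 and the lysosome. Whether the numbers pair the libraries stays open. Deviations of same-numbered libraries from their group means correlated at 0.018, -0.077 and 0.46. The best matches of vehicle 1, 2 and 3 were AZD1775 2, 1 and 3 (0.16, 0.32 and 0.46). Deviations within a group balance out, so these correlations depend on each other and cannot decide it. Genes near 1 CPM rested on few counts, such as Cxcl9 with 8 to 15 per library.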

Other observations

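Chosen after the results were seen were the tests of biological process terms, of the other splits of the libraries, of random matched lists, of markers set against each other, and of scores set against depth or maturation, while leaving out a library and fry were fixed beforehand. Camera was run over the 1113 biological process terms of the authors' gene annotation with 15 to 200 tested genes. With its preset correlation 122 terms passed, 70 higher and 52 lower in AZD1775, and with an estimated correlation or in fry 0 passed (camera, adjusted p = 0.816 with an estimated correlation for each term named here). The term with the smallest p was phagocytosis, recognition (28 genes, mean log2 fold change 0.76, camera adjusted p = 7.12e-13), followed by B cell receptor signalling (51 genes, 0.55, camera adjusted p = 9.54e-12). Both hold the same 20 immunoglobulin genes, whose reads can be shared and whose median was 1.01, against 0.49 and 0.20 for the 8 and 31 other genes, so the first term largely repeats the immunoglobulin values. The lower terms included chromosome segregation (81 genes, -0.16, camera adjusted p = 3.66e-07), and also protein folding (99 genes, -0.10, camera adjusted p = 0.000385), which overlaps the unfolded protein response and heat shock lists. No fixed list was made for mRNA splicing via the spliceosome (195 genes, -0.09, camera adjusted p = 0.000114) or ubiquitin-independent proteasomal catabolism (28 genes, -0.19, camera adjusted p = 0.000404), which were lower as well.

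Several genes outside the fixed lists had values apart in all 6 libraries and are named after their values were seen. Fcmr, the receptor for the Fc part of IgM, stood at 16.2 ± 1.95 CPM in vehicle and 31.7 ± 5.58 in AZD1775 (SD, n = 3), and Jchain, the joining chain of polymeric antibodies, at 20.1 ± 1.76 and 35.4 ± 5.33. Cep89, a gene of centriole appendages, stood at 14.5 ± 1.601 and 7.14 ± 1.18 CPM, 2.02-fold lower. Serpine2, a protease inhibitor, stood at 0.19 ± 0.19 and 1.58 ± 0.53 CPM, and the sulfotransferase gene Chst2 at 1.21 ± 0.33 and 3.75 ± 0.56. None passed edgeR's test (adjusted p = 0.291 for Fcmr, Jchain, Cep89 and Chst2 and 0.305 for Serpine2), but all 5 were called by DESeq2 (adjusted p = 0.000463, 0.00119, 0.000979, 0.00431 and 0.00916) and by edgeR without its filter on low counts. Both of these tests called more genes in a split of the libraries that mixed the treatments, given below. Serpine2 in vehicle 1 and 2, at 0.054 and 0.11 CPM, lay below what a count of 0 allows.

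The 6 libraries split into 3 against 3 in 10 ways, too few for a share under 0.05. In edgeR each of the 10 splits called 0 genes, so 10 gave as many as the real one, and the highest of the others was 0. At an unadjusted p under 0.05, 2 of the 10 splits, the real one with its 1124 genes among them, gave at least that many, and the highest other gave 2200. For DESeq2 it was again 2, the real one with 63 genes among them, and the highest other gave 361. Without its filter on low counts, edgeR called 478 genes in the real split and 822 in the highest other. Camera's preset called 24 lists in the real split, which was the only 1 of the 10 with that many, and the highest other called 21. The split with the most genes set vehicle 1, vehicle 2 and AZD1775 1 against vehicle 3, AZD1775 2 and AZD1775 3, which points to a structure of the samples that does not follow the treatment. It had the highest difference in the maturation list, at 0.53 against 0.43 in the real split. For 15 of the 24 lists called, another split gave a larger difference than the real one, and for 9 of those 15 the largest was in this split, among them cytokines (0.59 against 0.52) and interferon-stimulated genes (0.34 against 0.27). The real split gave the largest difference of the 10 for 10 of 39 lists, with an exact p of 0.1, the smallest it can be. Among them were mitosis (0.39, highest other 0.32), p53 targets (0.31, 0.18), ATF4 targets (0.40, 0.27), the unfolded protein response (0.20, 0.10) and B cell markers (0.82, 0.62).

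Explanations by gene length and expression level do not account for the lower mitosis genes: over 10000 random lists matched on both, the lowest median was -0.1058, above the median of -0.42 for mitosis. Vehicle 2, the library with the most ribosomal RNA reads, is not alone the reason, since without it the mean was still -0.3049 (camera past the threshold). A lower depth acting through each gene's count would move genes of like expression alike, but over 10000 lists matched on expression alone the lowest median was -0.1208. A difference between the libraries that goes with their depth stays open: totals do not overlap between the groups, and over the AZD1775 libraries they correlated with the mitosis score at r = 0.983 (scores of -0.63, -0.38 and -0.18 from the smallest total to the largest), against -0.178 over the vehicle libraries. The drug treatment stays open as well, as an untested biological reason.

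The higher B cell markers were set against 3 explanations. Shared reads among immunoglobulin genes do not account for them, since the 7 other markers had a median log2 fold change of 0.9286 and were all above 0.69. A lower share of dendritic cells, which would raise the markers of other cell types alike, stays open: 42 markers of 8 other types had a median of 0.3235 (SD 0.52), with macrophage markers at 0.71 and 3 T and NK cell markers at 0.92, and monocyte, neutrophil and stromal markers at -0.0057, -0.03 and 0.0049. A larger share of B-lineage cells stays open. The 7 markers differed from each other with an SD of 0.1145, less than the median SE of 0.194 of a single marker. That cannot decide it, since the SE holds variation between libraries that the markers share, which the SD leaves out. Whether such a share comes from the treatment or from the cultures each library began with was not tested.

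The higher ATF4 targets were set against 2 explanations. Unfolded proteins in the endoplasmic reticulum would raise the unfolded protein response list, whose median was -0.2055, and which fell (fry, adjusted p = 0.00913). With an estimated correlation that list did not pass (camera, adjusted p = 0.0944). Its exact p over the splits was 0.1, the smallest it can be. The fall speaks only to the genes of that list. The maturation state of the cultures stays open: at equal maturation score the groups differed in the ATF4 score by 0.2991, with a 95% interval from -0.11 to 0.71, against 0.40 without that adjustment. Over the vehicle libraries the maturation score had a range of 0.69 and the ATF4 score of 0.052, and vehicle 3 lay above AZD1775 1 and 2 in maturation (0.409 against 0.26 and 0.29) but below them in ATF4 (0.026 against 0.401 and 0.221), while AZD1775 3 was highest in both scores. The treatment stays open as an untested reason.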
